A study of Homo sapiens with 17 samples.

How the data were processed

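The series holds 17 libraries of cultured breast cancer cell lines, made with a droplet kit that tags the 3′ end of polyadenylated RNA and gives each captured molecule a unique molecular identifier (UMI). The labels name 13 lines. MCF7 has 3 libraries, labelled MCF7s1r1, MCF7s1r2 and MCF7s2 and called replicates 1, 2 and 3 here, and every other line has 1 untreated library. MDAMB436 and MDAMB453 each have 1 further library labelled Treated. The labels name neither the agent nor its dose or duration, and the series' design text calls the libraries unreplicated. Nothing in the labels says that the 3 MCF7 libraries came from separate cultures, so their spread may be technical.

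The deposited matrices hold UMI counts per gene and barcode, as whole numbers with no normalization. Per the file headers they were written by Cell Ranger 3.0.2 in 4 libraries (MCF7 replicate 1, MDAMB436, MDAMB453 and SUM190) and by Cell Ranger 3.1.0 in the other 13, which include both Treated libraries. The labels name version 3 of the kit for all libraries. The barcodes shared by chance between libraries imply a list of 0.731 M barcodes (0.590 to 0.918) in the 3.0.2 libraries. In the 3.1.0 libraries they imply 2.92 M (2.51 to 3.41). Pairs across versions shared 9 barcodes where 160 were expected from the larger list. These values argue against 1 barcode list for all libraries, so the 3.0.2 libraries may come from a different kit. The labels' protocol names Cell Ranger 3.1.0 for all, and the submitters' processing notes name Cell Ranger 3.0.2, Seurat and the genome build GRCh38. The barcode filter behind the deposited matrices is not given in the sources used here beyond these tools. Each matrix has the same 33538 gene identifiers. Coordinates are on GRCh38 from the GENCODE 29 annotation, to which 33456 identifiers (99.8%) were matched. 2 symbols of the fixed gene lists belong to more than 1 identifier, and the identifier with more UMIs was used.

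The deposited matrices hold 48556 barcodes and the labels state 36195 cells. The filter used here kept barcodes with at least 500 detected genes and at most 20% of UMIs from the 13 mitochondrially encoded genes, which left 36174. It removed 12382 barcodes, 10818 of them above the mitochondrial limit and 2649 below the gene minimum, with some barcodes failing both. Doublets were called with Scrublet in scanpy 1.11.5. It marked 884 of 1233 kept BT474 cells (71.7%), which is not a workable result for that library, and 205 cells in the other 16 libraries, between 0.0235% and 7.65% of each. Doublets were therefore left in, and leaving out the calls was an alternative.

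UMI counts were summed over the kept cells of each library and scaled by the library total to counts per 1e+06 UMIs (CPM). Cells were not used as replicates. Kept totals ran from 7.70 M UMIs in SKBr3 (353 cells) to 92.4 M in BT549 (3010 cells), so at the smallest total 3 UMIs correspond to less than 1 CPM. Fold changes are log2 ratios of CPM with a pseudocount of 1 CPM. Linear ratios and levels carry exact Poisson 95% intervals, and shares of cells carry exact (Clopper-Pearson) binomial 95% intervals. All of these intervals cover counting error only.

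Each treated comparison has 1 library per condition. No test was made and no p-value is given. A test with the spread borrowed from the MCF7 libraries was left out, because it would assume that the treated lines vary as MCF7 does. "Higher" and "lower" describe the pair of libraries measured. Genes were counted as apart when they differed by at least 4-fold and reached 50 CPM in either library. The same count was made for each pair of MCF7 libraries as the measure of spread between libraries labelled as the same line. For 47 gene lists, the median log2 fold of the members with at least 5 CPM was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list needed 5 measured members, and percentiles at or below 2.5 or at or above 97.5 were called low or high. The main scaling was to total UMIs. TMM factors (edgeR 4.0.16) and size factors (DESeq2 1.42.0, both in R 4.3.3) served only as alternative scalings.

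Named genes were the 12 highest and 12 lowest folds of each comparison among genes with at least 50 CPM, and the 4 members with the largest fold in each list called. Across lines they were a receptor list, members of the fixed lists, and the 3 genes per line with the largest log2 gap to the next line among genes with at least 100 CPM. Within lines they were the 5 genes with the highest Fano factor outside the cell cycle and histone lists, and for regions at most 3 per line. This rule, the lists, the tests of the main results and 25 of the alternatives were fixed before the data were examined. A further 9 alternatives were added later, as were the tests of flagged results that are named below as chosen afterwards.

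Shares of cells with a marker UMI and Fano factors (variance over mean of UMI counts) were computed after thinning each cell to 5000 UMIs, leaving out shallower cells. Genes with a mean of at least 0.1 thinned UMI and a Fano factor of at least 3 were counted as overdispersed. Relations between 2 measures across the 13 lines, with MCF7 as the mean of its libraries, were tested with two-sided permutation tests of 100000 resamples for Pearson's r and Spearman's rho, adjusted by the Benjamini-Hochberg method over the family of 10. These p-values measure the spread between the lines only. They treat the libraries labelled MDAMB231 and MDAMB361 as separate lines, which their similarity puts in doubt. Regional expression was the median log2 ratio to the median line over windows of 25 neighbouring genes with at least 10 CPM in any library, and a median of at least 1.5 named a region. Each cell was assigned to the line profile with the highest multinomial likelihood over genes with at least 50 CPM in any line. An untreated cell contributes to its own line's profile. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

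Each step was tested on simulated data. With counts drawn from the MDAMB436 library over 2684 genes, the 4-fold rule called 0 of 68 genes raised by a log2 of 1.2, 68 of 68 raised by 2.2 and 64 of 64 raised by 3.2, and none of the unchanged genes. For MDAMB453 over 2714 genes the numbers were 0 of 68, 67 of 68 and 64 of 64. Gene lists shifted by a log2 of 1 were called in 20 of 20 simulations in each line, and unshifted lists in 5 of 100 (MDAMB436) and 8 of 100 (MDAMB453). The Fano rule found 200 of 200 overdispersed genes among 1401, the permutation test called 18 of 400 unrelated pairs, and 520 of 520 simulated cells were assigned to their line at 600 UMIs. The simulated cells were drawn from the profiles used to assign them, and the simulated counts of a line from its single library. These rates therefore leave out the spread between libraries and the departure of real cells from their line profile.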

Results

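Single-cell RNA profiles were collected from 13 breast cancer cell lines in 17 libraries. The lines were BT474, BT549, HCC1954, MCF7, MDAMB231, MDAMB361, MDAMB436, MDAMB453, MDAMB468, SKBr3, SUM149, SUM190 and T47D. The series' stated purpose covers subtyping, heterogeneity, stemness and the testing of therapies. After filtering, 36174 cells remained, and the median depth per kept cell ran from 6025 UMIs in MDAMB453 to 36518.5 in the library labelled MDAMB361. BT474 kept 1233 of 4210 barcodes and T47D 1354 of 5539, because most of their barcodes exceeded the mitochondrial limit. Outside MCF7 each condition had 1 library, so no difference between lines or between treated and untreated libraries has a replicate check.

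The receptors that define clinical subtypes separated the lines. ERBB2 (HER2; ENSG00000141736, chromosome 17, 39687914 to 39730426) was highest in HCC1954 at 1236 CPM (counting interval 1228 to 1243), followed by BT474 at 1148, SUM190 at 947 and SKBr3 at 805. MDAMB453 had 262 CPM, and no other untreated library exceeded the 57.4 CPM of T47D. ESR1, the oestrogen receptor (ENSG00000091831, chromosome 6, 151656691 to 152129619), reached 60.2 CPM in T47D and 97.4 ± 127 CPM in MCF7 (SD, n = 3). Its values in the MCF7 libraries were 51.3, 241 and 0.0327 CPM. PGR, the progesterone receptor and an oestrogen receptor target, was highest in T47D at 122 CPM. The androgen receptor AR stood at 404 CPM in MDAMB453, against 85.7 CPM in BT474, the next line. EGFR (chromosome 7, 55019021 to 55211628) reached 1664 CPM in MDAMB468, against 165 CPM in BT549. Other receptors marked particular lines, with the prolactin receptor PRLR at 657 CPM in T47D and FGFR4 at 531 CPM in MDAMB453. FGFR1 was highest in BT549 at 133 CPM, with a smaller gap to the 70.6 CPM of MDAMB231.

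**Figure D1:**
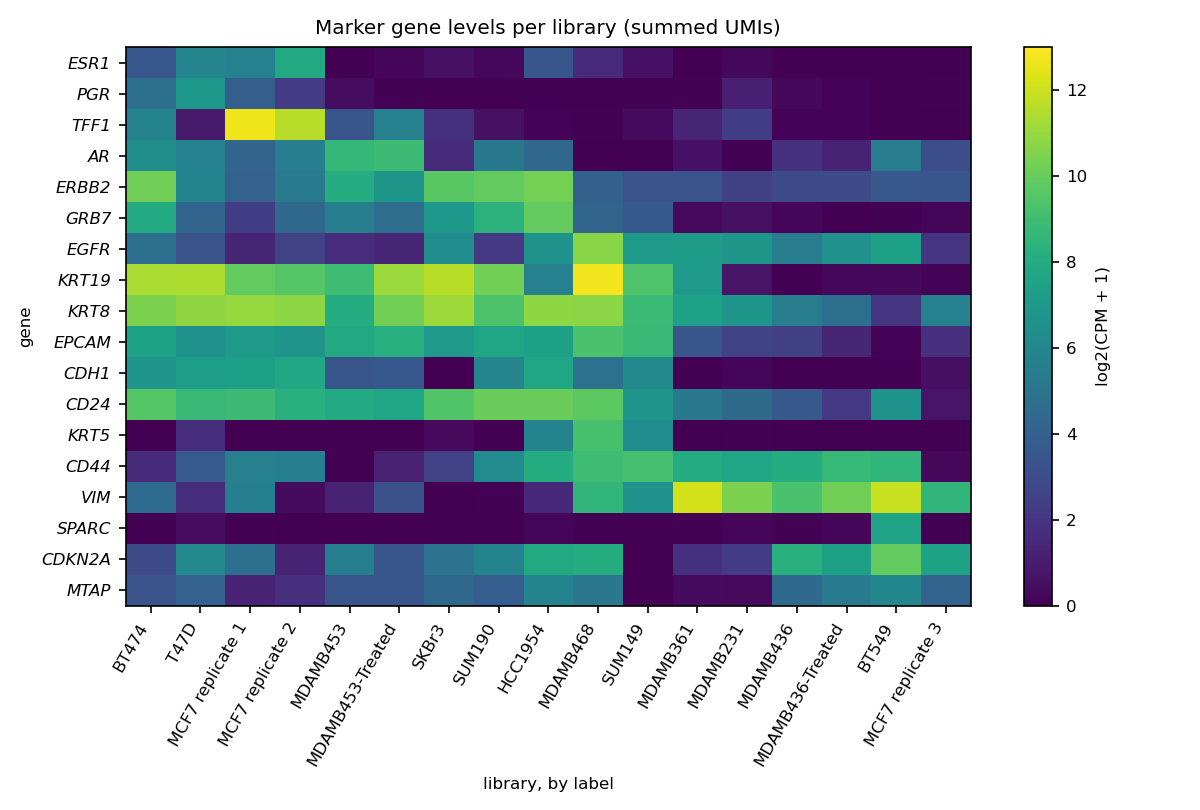
Level of 18 marker genes (vertical axis) in each of the 17 libraries (horizontal axis, by label), as log2(CPM + 1) of summed UMIs on the colour scale. ERBB2 is brightest in HCC1954 (1236 CPM), BT474 (1148 CPM), SUM190 (947 CPM) and SKBr3 (805 CPM), and EGFR in MDAMB468 (1664 CPM).

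Epithelial, mesenchymal, luminal and basal genes differed widely between the libraries. The epithelial list, which holds the adhesion molecules EPCAM and CDH1 and several claudins and keratins, had a mean log2(CPM + 1) between 6.03 and 7.08 in SUM149, SKBr3, SUM190, MDAMB453, MDAMB468, BT474, HCC1954, T47D and MCF7 replicates 1 and 2. It was 0.38 in BT549, 1.21 in the library labelled MCF7s2 (MCF7 replicate 3), 1.34 in MDAMB436, 2.21 in MDAMB231 and 2.80 in the library labelled MDAMB361. EPCAM was 454 CPM in SUM149 and 0.0866 CPM in BT549. The mesenchymal list did not divide the libraries in the same way, since it was 2.98 in SUM149 and 2.53 in MDAMB231. It was highest in BT549 at 5.31, where the intermediate filament gene VIM had 3872 CPM and the collagen gene COL1A2 261 CPM. The basal list was highest in SUM149 (5.63), MDAMB468 (5.45) and HCC1954 (4.93), and the basal keratin KRT5 had 588 CPM in MDAMB468. The luminal list was highest in BT474 (7.07) and T47D (7.06), and the luminal transcription factor GATA3 had 645 CPM in T47D against 2.81 CPM in MDAMB436. The oestrogen receptor target TFF1 was 6586 and 3101 CPM in MCF7 replicates 1 and 2 and 0.0164 CPM in replicate 3. SKBr3 had 0 UMIs of CDH1, for which the counting interval reaches 0.479 CPM.

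Each line also had genes with large gaps to every other line. T47D had 607 CPM of SERPINA6, which encodes corticosteroid-binding globulin (chromosome 14, 94304248 to 94323394), against 0.329 CPM in the next line, and 551 CPM of the apolipoprotein gene APOE. The cancer-testis antigen gene MAGEA4 (chromosome X, 151912509 to 151925170) had 578 CPM in MDAMB436 and 0.407 CPM in MDAMB468. FAM9C had 318 CPM in HCC1954, and the keratin gene KRT15 2502 CPM. WFDC2 reached 2306 CPM in SUM149 and the metallothionein gene MT1G 658 CPM in SUM190. MDAMB231 was marked by KISS1, a metastasis suppressor gene, at 1245 CPM against 7.05 CPM in MDAMB453. BT549 was marked by COL1A2 and SPARC (195 CPM), MDAMB453 by FABP7 (109 CPM), FGFR4 and CLCA2 (432 CPM), and MDAMB468 by the epidermal caspase gene CASP14 (854 CPM). SKBr3 had 124 CPM of CTAG2, another cancer-testis antigen gene, against 0.0479 CPM in MDAMB468.

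ERBB2 moved with its chromosomal neighbours across the lines. Log2 ERBB2 and the mean of 12 neighbouring genes, among them GRB7, STARD3 and MIEN1, correlated with r = 0.932 (two-sided permutation p = 3e-05, adjusted p = 0.0003, n = 13) and rho = 0.808 (permutation p = 0.00157, adjusted p = 0.00785). Without BT474 and HCC1954, the lines farthest from the median, r was 0.935. Among the 10 lines with a library from Cell Ranger 3.1.0, ERBB2 fell into separate clusters. The larger cluster of 7 lines gave r = 0.650 (permutation p = 0.133).

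Epithelial and mesenchymal list means were inversely related, with r = -0.804 (permutation p = 0.00115, adjusted p = 0.00575, n = 13) and rho = -0.670 (permutation p = 0.0147, adjusted p = 0.0491). Without BT549 and MDAMB436 r was -0.677, and within the 10 lines of version 3.1.0 it was -0.822 (permutation p = 0.00315). Without MCF7 replicate 3, or without the library labelled MDAMB361, the lines formed separate clusters on this axis, and r within the larger cluster was -0.414 and -0.276. ESR1 correlated with its target genes at r = 0.782 (permutation p = 0.00256, adjusted p = 0.0064), but rho was 0.608 (permutation p = 0.0322, adjusted p = 0.0806) and r was 0.403 without MCF7 and T47D, so the relation rests on those lines. Under the stricter filter and the average over cells the lines split into clusters, and r in the larger cluster was -0.233 and 0.0928. ESR1 and PGR gave r = 0.789 (permutation p = 0.00373, adjusted p = 0.00746) and rho = 0.343 (permutation p = 0.247, adjusted p = 0.412), and r was 0.564 without MCF7 and T47D and -0.286 and -0.140 in the larger cluster under the same alternatives. Within version 3.1.0 these relations had r = 0.839 (permutation p = 0.00358) and r = 0.762 (permutation p = 0.0104).

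The G2/M phase list rose with the share of thinned cells holding a UMI of the proliferation genes MKI67 or TOP2A, at r = 0.768 (permutation p = 0.00229, adjusted p = 0.0064) and rho = 0.841 (permutation p = 0.00057, adjusted p = 0.0057). Without BT474 and SKBr3 r was 0.670, and within version 3.1.0 it was 0.777 (permutation p = 0.00845). The G2/M list itself holds MKI67 and TOP2A, so part of the relation is built in. Its call was the same when they were left out of the list. The other 5 relations of the family did not pass in permutation tests with adjustment. AR with androgen receptor targets had r = 0.344 and rho = 0.292 (adjusted p = 0.384 and 0.413), ESR1 with EGFR r = -0.290 and rho = -0.304 (0.422 and 0.413), CD24 with CD44 r = -0.326 and rho = -0.176 (0.384 and 0.617), luminal with basal genes r = -0.0329 and rho = -0.154 (0.912 and 0.617), and median UMIs with the mitochondrially encoded share r = 0.0391 and rho = 0.352 (0.912 and 0.412). Within version 3.1.0, ESR1 with EGFR gave r = -0.666 (permutation p = 0.0356, adjusted p = 0.0569). Across both versions its r was 0.146 without MCF7 and T47D. Under the stricter filter and the average over cells the lines split into clusters, and r in the larger cluster was 0.635 and 0.521. The 3.0.2 libraries hold only 3 lines besides MCF7, too few for a value. Without the library labelled MDAMB361, 9 relations of the family kept their call, and the epithelial with mesenchymal relation split into clusters.

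Windows of 25 neighbouring genes named 24 regions of joint high expression. BT474 had 5. The strongest spanned 36088256 to 40648864 on chromosome 17 and included ERBB2, IKZF3 and PGAP3, with a best window at a median log2 ratio of 3.70 to the median line. Another BT474 region, from 57255851 to 63446378, held TBX2, TRIM37 and BCAS3, and MCF7 had a region from 58692573 to 63741986 with BCAS3, TRIM37 and PPM1D (best median 1.81, or 2.86 without the libraries labelled MDAMB361 and MCF7s2). SKBr3 had a shorter region around ERBB2, from 38752736 to 40501597 (2.09). EGFR and its neighbours LANCL2 and SEC61G were jointly high in MDAMB468 (chromosome 7, 44983023 to 65006743, 1.95). SUM190 had a region on chromosome 22 with MED15 and SNAP29 (19431902 to 22559361, 2.71), and HCC1954 a region on the short arm of chromosome 9 with CD274, which encodes PD-L1 (14521 to 23826337, 2.23). HCC1954, SUM190 and MDAMB453 had no named region at ERBB2, although GRB7, ORMDL3 and MIEN1 next to it were high in HCC1954 (log2 ratios of 5.68, 5.58 and 4.25).

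**Figure D2:**
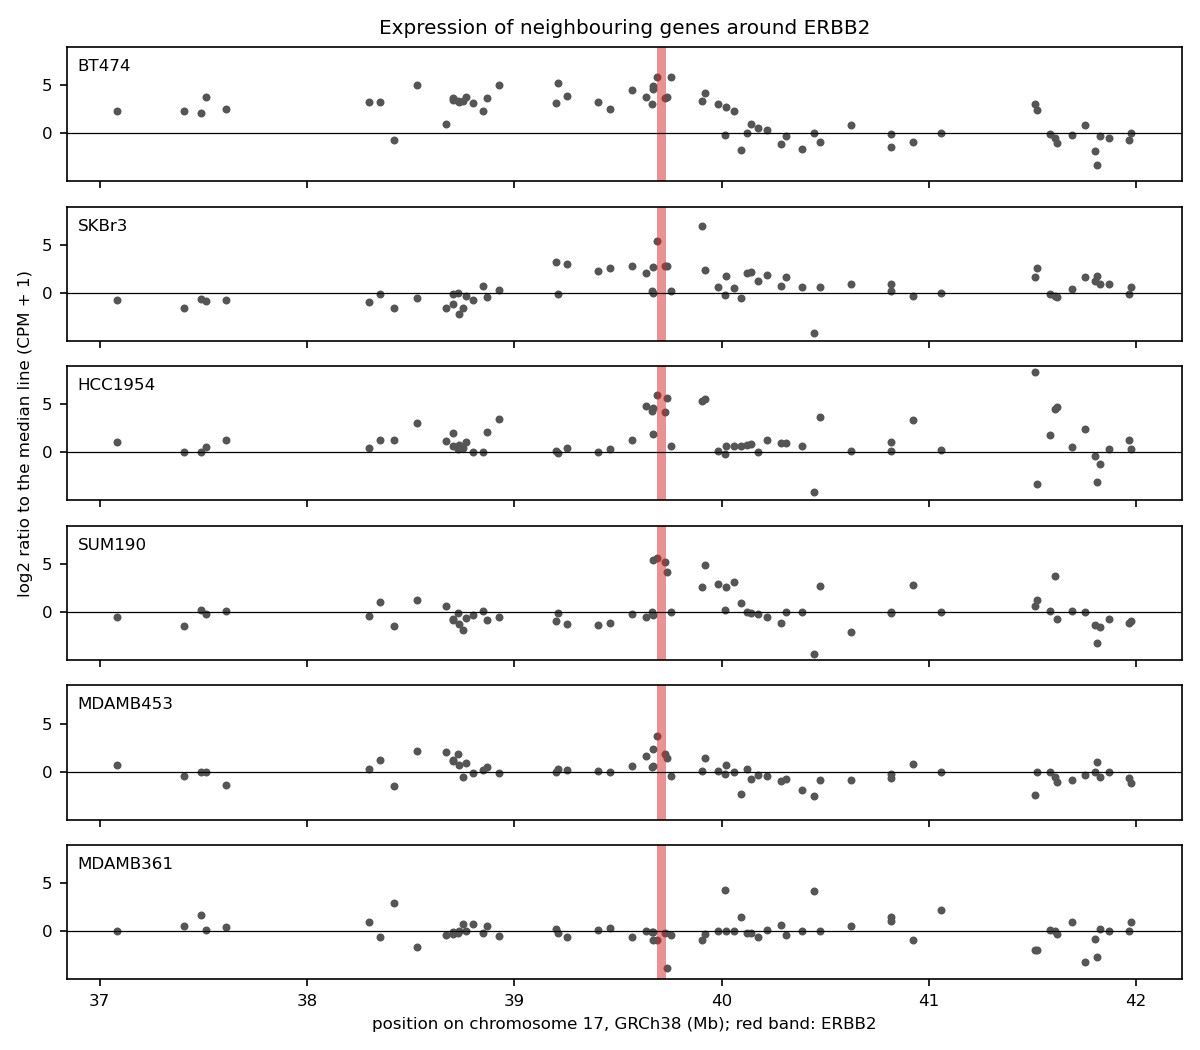
Log2 ratio of each gene's CPM + 1 to the median line (vertical axis) along chromosome 17 on GRCh38 in Mb (horizontal axis) in 6 untreated libraries. Each point is a gene and the red band marks ERBB2. Genes on both sides of ERBB2 are high in BT474, where the region spans 36088256 to 40648864, the raised stretch is shorter in SKBr3, HCC1954 and SUM190, and the library labelled MDAMB361 shows none there, with ERBB2 at 9.07 CPM.

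Whole profiles were compared between all libraries. Across 6156 genes, which are not independent replicates, BT474 was nearest T47D (r = 0.806), HCC1954 nearest MDAMB468 (r = 0.774) and BT549 nearest the MDAMB436-Treated library (r = 0.809). SUM190 was nearest HCC1954 (r = 0.758) and SUM149 nearest the library labelled MDAMB361 (r = 0.790). MDAMB231 and the library labelled MDAMB361 reached r = 0.928, against a median of 0.663 for pairs of different lines and 0.8197 for the next such pair. Between these libraries, 74 of 3541 genes (2.09%) differed by at least 4-fold. KISS1 was 1245 CPM in MDAMB231 and 0.832 in the library labelled MDAMB361, and HLA-B 769 and 94.8 CPM. The keratin gene KRT19 was 0.635 and 129 CPM, PRSS3 5.34 and 188 CPM, and NRG1 6.20 and 64.5 CPM.

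The MCF7 libraries differed from each other by far more than counting error. Chi-square per degree of freedom was 908 for replicates 1 and 2, 1286 for 1 and 3 and 929 for 2 and 3, so no pair was treated as copies of a single library. Replicates 1 and 2 had r = 0.855 and both expressed GATA3 (594 and 1378 CPM), EPCAM (131 and 104 CPM) and KRT8 (1934 and 1760 CPM). The library labelled MCF7s2 (replicate 3) had r = 0.704 and 0.638 with them and was nearest BT549 at 0.761. It had 3.97 CPM of GATA3, 2.502 of EPCAM and 51.7 of KRT8, and 381 CPM of VIM. Every value for the MCF7 line includes it.

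Markers used to describe stem-like breast cancer cells differed widely between lines. After thinning to 5000 UMIs, a UMI of CD44 without any of CD24 was found in 53.5% of BT549 cells (exact binomial interval 51.6 to 55.4), 51.8% of MDAMB231, 58.5% of SUM149 and 63.1% of MDAMB436. The share was 3.17% in MDAMB468, where both genes were abundant, and 0 of 1077 cells in BT474, for which the exact interval reaches 0.342%. ALDH1A3, an aldehyde dehydrogenase gene, was found in 85.2% of HCC1954 cells and 45.7% of SUM149 cells, and the stem cell marker PROM1 in 8.04% of SUM190 and 7.79% of MDAMB468 cells. No background share from free RNA was measured for these markers, so low shares may not mark cells that express the gene. ERBB2 was found in 99.1% of BT474 cells and in 5.50% of BT549 cells, and EGFR in 99.4% of MDAMB468 and 1.13% of MDAMB453 cells. Without thinning the CD44-only share was 26.2% in BT549, 19.0% in SUM149 and 72.9% in MDAMB436, at median depths of 31410, 31598 and 9880 UMIs.

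Within a library, a median of 74 genes varied more between cells than the Fano limit, and 69 without cell cycle and histone genes. The count ran from 18 in the library labelled MCF7s2 to 267 in MDAMB231. The nuclear RNAs MALAT1 and NEAT1 and the mitochondrially encoded MT-ATP6, MT-CO2 and MT-CO3 passed in all 17 libraries. The calprotectin genes S100A8 and S100A9 and their relative S100A7 led in HCC1954 (Fano factors of 88.4, 60.7 and 125), and S100A8 led in SUM190 (153). The interferon-induced gene ISG15 led in the library labelled MDAMB361 (114), and IFIT2 was found in 2.33% of MDAMB231 cells with a Fano factor of 41.4. In MDAMB436 the chemokine gene CCL3 was found in 14.6% of cells (35.5) and DHRS2 in 1.05% (78.9). The secretory genes MUCL1 and SCGB2A2 varied in BT474, where they were found in 45.7% and 25.5% of cells.

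In MDAMB436, interferon-induced genes were lower in the treated library. Of 23 measured members of the interferon response list 23 were lower and 19 were at least 2-fold lower, with a median log2 fold of -1.65 at percentile 0 of the matched random lists. IFI44L was lower by 15.5-fold (counting interval 11.8 to 20.8), IFI6 by 10.0-fold (9.24 to 10.9), ISG15 by 6.999-fold (6.81 to 7.19) and IFIT1 by 7.42-fold (6.61 to 8.34). Among the highest folds, IGFBP3, an insulin-like growth factor binding protein (chromosome 7, 45912245 to 45921874), had 0.176 CPM untreated and 52.4 CPM treated (log2 fold 5.51), and the collagenase gene MMP1 (chromosome 11, 102789920 to 102798160) 9.95 and 451 CPM (5.37).

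Among other genes, the EGFR ligand gene EREG was higher by a log2 fold of 4.33, the interleukin receptor gene IL13RA2 by 4.35, the cytochrome P450 gene CYP1B1 by 4.05, AKR1C1 by 3.67, EFNB2 by 3.66, KCNMA1 by 3.59, DNER by 3.34, SERPINB2 by 3.18, IGFN1 by 2.79 and S1PR3 by 2.56. The lowest folds were MTRNR2L8 (-6.15), MIR4458HG (-3.92), IFI6 (-3.25), ISG15 (-2.80), C15orf48 (-2.78), IFIT1 (-2.76), ISG20 (-2.72), AC103591.3 (-2.69), BEX5 (-2.68), BST2 (-2.46), SMIM4 (-2.41) and the chemokine gene CCL5 (-2.38). MTRNR2L8 had 3373 and 2 UMIs, a ratio of 1382 (counting interval 382 to 11417). It is near-identical to mitochondrial ribosomal RNA, so its counts are uncertain, and it was also lower in MCF7 replicate 2 than in replicate 1 by a log2 of 3.49. AC103591.3 is uncertain too, because reads of overlapping genes may be split. Between the same MCF7 replicates ISG20 (-2.83), C15orf48 (-2.14), ISG15 (-1.39) and IFI6 (-1.22) were also lower, while IFIT1 (1.08) and SMIM4 (1.96) were higher. Smaller drops there were seen for AC103591.3 (-0.77), CCL5 (-0.76), BEX5 (-0.53), BST2 (-0.53) and MIR4458HG (-0.42). Of the highest folds, IGFBP3 (2.82), EFNB2 (2.03), CYP1B1 (1.08) and S1PR3 (1.03) were also higher there. KCNMA1 (-2.51), EREG (-0.57), DNER (-0.51) and AKR1C1 (-0.43) were lower there.

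Of 40 measurable lists in MDAMB436, 14 were high and 3 low. Between MCF7 libraries 4 lists were high and 5 low of 41 for replicates 1 and 2, 5 and 22 of 40 for 1 and 3, and 4 and 20 of 40 for 2 and 3. Lists beyond the limits thus also arise between untreated libraries labelled as 1 line. Besides the interferon list, metallothioneins were low (5 of 6 lower, median -1.36, with MT1A at -2.41, MT1E at -1.86 and MT2A at -1.42), as was antigen presentation (10 of 11 lower, median -0.46, percentile 1.52, with TAP1 at -0.92 and HLA-B at -0.83). The mesenchymal list was high, with 14 of 19 members higher and a median of 1.12, led by PRRX1 (2.79), COL6A1 (2.19) and MMP2 (2.18). Receptors were high with 8 of 8 members (median 0.98, EGFR 1.07, IGF1R 1.22), the basal list with 7 of 8 (median 0.90, FOXC1 1.73 but S100A2 -1.76), Wnt targets with 5 of 6 (median 0.83, CCND1 1.25) and DNA repair with 21 of 27 (median 0.50, XRCC5 1.51, BRCA1 1.09). Heat shock genes (13 of 14, median 0.72, HSPH1 1.38 but HSPB1 -2.28), NRF2 targets (13 of 17, median 0.66, TXNRD1 1.52) and xenobiotic metabolism (8 of 8, median 0.76, MGST1 1.39) were also high.

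The smaller high medians in MDAMB436 were senescence secretory genes (13 of 18 higher, 0.51, MMP3 3.53), tumour suppressors (14 of 18, 0.55, NF1 1.00), stemness genes (8 of 13, 0.57, SOX9 1.74 but CD24 -1.48), MAPK output (18 of 22, 0.47, DUSP4 1.33) and S phase genes (34 of 42, 0.34, NASP 1.00). Mitochondrially encoded genes were high at 0.91, with 11 of 13 members higher. When only cells with 8 to 20% mitochondrially encoded UMIs were compared, this list and the senescence, tumour suppressor, stemness and MAPK lists were no longer beyond the limits. Wnt targets were lost when CPM were averaged over cells (percentile 96.7), xenobiotic metabolism with members of at least 50 CPM (97.3) and mitochondrially encoded genes also under the stricter filter. S phase was lost in 5 of 14 settings: no cell filter, the stricter filter, a 40% mitochondrial limit, the average over cells and a pseudocount of 5 CPM. MAPK output was also lost under the stricter filter and without shared barcodes, stemness under the stricter filter, the average over cells and the minimum of 50 CPM, and senescence secretory genes without shared barcodes and at that minimum. Antigen presentation was lost under the stricter filter and with members of at least 50 CPM, at a percentile of up to 4.33.

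In total 26 genes were at least 4-fold higher and 23 at least 4-fold lower in treated MDAMB436, of 3253 measured. Pairs of MCF7 libraries differed at more genes, with 170 and 159 of 2762 for replicates 1 and 2, 332 and 265 for 1 and 3, and 321 and 410 for 2 and 3. The MDAMB436 counts therefore lie below those of every MCF7 pair. No MCF7 pair is a clean reference. Replicates 1 and 2 differ in Cell Ranger version and barcode list, and the other pairs include the library labelled MCF7s2, whose label is in doubt. TMM scaling moved the median fold by -0.12 and gave 18 higher and 28 lower genes, so the higher share went from 53.1% to 39.1%. Both untreated libraries came from Cell Ranger 3.0.2 and both treated ones from 3.1.0, so treatment cannot be told apart for any single pair from version, or from whatever lies behind the smaller barcode list of the 3.0.2 libraries, which may be another kit.

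**Figure D3:**
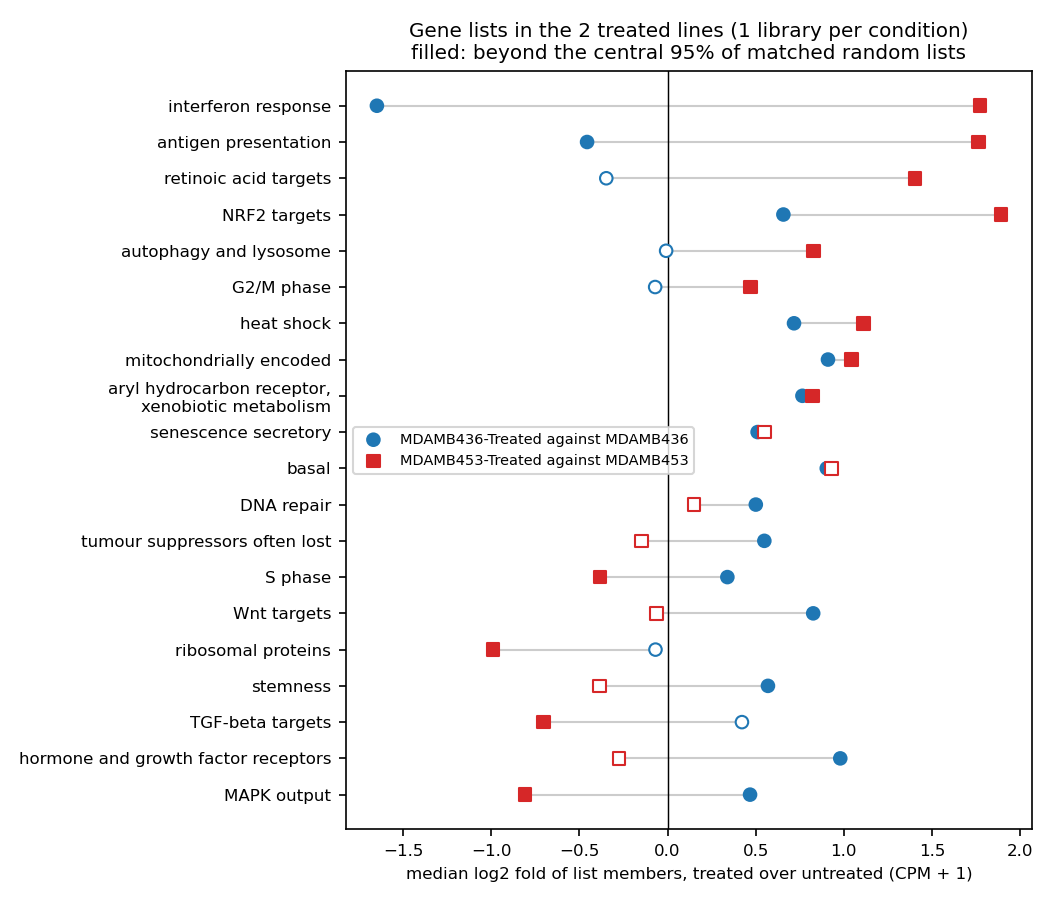
Median log2 fold of the members of each list, treated over untreated (horizontal axis, pseudocount of 1 CPM), for the gene lists measured in both lines and beyond the limits in at least 1 of them (vertical axis), with 1 library per condition. Filled points lie beyond the central 95% of matched random lists. The interferon response list sits at -1.65 in MDAMB436 and at 1.77 in MDAMB453, and NRF2 targets at 0.66 and 1.89.

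In MDAMB453, targets of the oxidative stress regulator NRF2 were higher in the treated library. Of 16 measured members 15 were higher and 13 at least 2-fold higher, with a median log2 fold of 1.89 at percentile 100. The haem oxygenase gene HMOX1 (chromosome 22, 35380361 to 35394214) had 3.94 CPM untreated and 199 CPM treated, a 50.6-fold difference (counting interval 43.5 to 59.0). G6PD, which starts the pentose phosphate pathway, was 11.9-fold higher (11.7 to 12.1), and the thioredoxin reductase gene TXNRD1 10.7-fold (10.3 to 11.2). AKR1C2 had 0 UMIs untreated and 22.9 CPM treated. Interferon and antigen presentation genes were higher too, opposite to MDAMB436. Of 19 interferon response genes 17 were higher (median 1.77, OASL 4.04, IFI27 3.59, IFI6 3.33, IFIT1 3.19). Of 11 antigen presentation genes 9 were higher (median 1.76, HLA-B 3.92, PSMB9 3.30, NLRC5 2.93, HLA-A 2.90). With members of at least 50 CPM only, the interferon list lay at percentile 79.5. Cell quality differed as well between the treated and untreated MDAMB453 libraries. The median mitochondrially encoded share of kept cells was 15.7% treated and 6.37% untreated, and 57.3% and 88.1% of barcodes were kept.

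Among the other highest folds were MT-ATP8 (5.21), AC108134.2 (5.14), TMEM238 (3.97), CLSTN3 (3.70), the autophagy receptor gene SQSTM1 (3.55), the epoxide hydrolase gene EPHX1 (3.54), COX16 (3.53) and TXNDC16 (3.40). MT-ATP8 overlaps MT-ATP6, so their counts are uncertain. MCF7 replicate 2 exceeded replicate 1 by 4.43 for TMEM238, 2.90 for AC108134.2, 2.55 for COX16 and 2.51 for MT-ATP8. It also did so by 1.86 for SQSTM1 and 1.15 for EPHX1, while HMOX1 (-0.998) and HLA-B (-0.71) were lower in replicate 2. The lowest folds were FABP7 (-5.46; 109 and 1.496 CPM), the BMP target genes ID1 (-5.15) and ID3 (-2.95), FGFR4 (-4.14; 531 and 29.1 CPM), C1orf56 (-3.65), SLC9A3R2 (-3.24), CLCA2 (-3.22), IGFBP5 (1492 and 186 CPM), SMARCB1 (-2.97), MYC (-2.92), THOC6 (-2.80) and TAX1BP3 (-2.79). FABP7, FGFR4 and CLCA2 were the genes that marked the untreated MDAMB453 library among the lines.

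Of 39 measurable lists in MDAMB453, 9 were high and 4 low. Autophagy and lysosome genes were high with 21 of 24 members (median 0.83, GPNMB 3.96, GABARAP 2.63, CTSA 2.22), heat shock genes with 14 of 15 (median 1.11, HSPB1 2.51, HSPA1A 1.92) and mitochondrially encoded genes with 11 of 13 (median 1.04). Xenobiotic metabolism was high with 8 of 10 (median 0.82, NQO1 2.18, CYP1A1 2.97), and both this list and the mitochondrially encoded one were lost under the stricter filter (percentiles 66.1 and 66.3). Under that filter CYP1A1 reversed to -1.47. Retinoic acid targets were high with 3 of 5 members (median 1.40, DHRS3 2.26 but CRABP2 -1.01). UGT1A6 had 1 UMI untreated and 175 treated, a ratio of 481 (85.2 to 19113). MAPK output was low, with 11 of 13 members lower (median -0.81, MYC -2.92, FOS -2.68, SPRED1 -2.53, SPRY4 -2.17), as were TGF-beta targets (11 of 14, median -0.70, ID1 -5.15, CTGF -2.39, SMAD7 -1.56). With members of at least 50 CPM MAPK output lay at percentile 4.06 and TGF-beta targets at 7.40, so neither was low. S phase genes were low with 30 of 42 (median -0.38, UHRF1 -2.62, UNG -2.01). G2/M genes were high with 36 of 54 (median 0.47, TUBB4B 1.92, but HMGB2 -2.19 and UBE2C -1.62), but their median was -0.09 when CPM were averaged over cells (percentile 13.2), and the call was also lost with no cell filter and with members of at least 50 CPM. Ribosomal protein genes were low with 33 of 35 (median -0.99, RPL7 -2.33), and their median was -1.35 in MCF7 replicate 2 against replicate 1, which differ in Cell Ranger version in the same way.

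In total 85 genes were at least 4-fold higher and 62 lower in treated MDAMB453, of 3373 measured, again below the counts between MCF7 libraries. TMM scaling moved the median fold by -0.18 and gave 59 higher and 86 lower genes, so the higher share went from 57.8% to 40.7%. In this treated library 235 of 1196 kept cells (19.6%, exact interval 17.4 to 22.0), holding 7.30% of its UMIs, were assigned to other lines, most often MCF7 (84 cells) and MDAMB231 (47 cells). In the other 16 libraries the share ran from 0.0811% to 4.44%. Without those cells the medians were 1.91 for NRF2 targets and 1.77 for interferon response genes.

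Across 4353 genes the treated folds of the lines correlated with r = 0.233, rho = 0.290 and covariance 0.161, and no library is shared between the comparisons. Both lines had 85 genes at least 2-fold higher, where independent lists would give 49.4, and 70 at least 2-fold lower against 28.5, while 40 went opposite ways. TIMP1, a metalloproteinase inhibitor gene, was higher by 2.23 and 2.33 (log2, MDAMB436 and MDAMB453), the ubiquitin ligase gene FBXO32 by 2.31 and 2.03, ANXA1 by 1.89 and 2.15, and GABARAP by 1.72 and 2.63. The folds also correlated with those of MCF7 replicate 2 over replicate 1, which likewise set version 3.1.0 against 3.0.2 and the larger barcode list against the smaller, at r = 0.196 in MDAMB436 and 0.317 in MDAMB453 across 4733 genes. Of 37 lists measured in both lines, 4 were high in both (NRF2 targets, heat shock, mitochondrially encoded, xenobiotic metabolism). NRF2 targets and heat shock stayed high in both lines under every alternative, while each of the other 2 was lost under some alternative in both lines. None of these alternatives separates treatment from Cell Ranger version or barcode list, which differ in the same way in both pairs. Of the 37, none was low in both and 4 went opposite ways (interferon response, antigen presentation, S phase, MAPK output). Each of these 4 calls was lost in at least 1 line under some alternative, interferon response only in MDAMB453 with members of at least 50 CPM.

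Fewer thinned cells held a UMI of MKI67 or TOP2A in both treated libraries. The share was 60.8% untreated and 51.3% treated in MDAMB436, a difference of -9.50 percentage points (interval -12.8 to -6.21), and 45.2% and 39.2% in MDAMB453, a difference of -5.97 (-9.67 to -2.23). These intervals cover counting error over the cells of 1 library per condition only. Thinning left out 676 and 107 shallower cells in MDAMB436 and 2060 and 197 in MDAMB453. Without thinning the difference was 2.36 points in MDAMB436, where median depth was 9880 untreated and 24872 treated, and -4.55 in MDAMB453. In MDAMB453 it was -0.16 after thinning to 2500 UMIs and -1.63 in cells assigned to their own line.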

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

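The tests of a shared version shift, of the identity of the library labelled MDAMB361, of a match of the library labelled MCF7s2 to another line, of chance barcodes and of carried-over reads were chosen after the result was seen, and the others before.

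Interferon response and antigen presentation genes were lower in treated MDAMB436 and higher in treated MDAMB453, with differences of medians (MDAMB453 minus MDAMB436) of 3.42 and 2.22 that were not tested, having 1 library per condition. Taken as 1 set they had medians of -1.13 (34 genes) and 1.77 (30 genes), and 0.30 between MCF7 replicates of different versions. A shift of equal size in both pairs, such as from the Cell Ranger version or the kit, would not give medians of opposite sign. The lists were picked for going opposite ways, so their difference of 2.90 is no independent test. A version or kit shift that acts differently in the 2 lines stays open. Cells of other lines in the treated MDAMB453 library are argued against by a difference of 2.89 in cells assigned to their own line. In cells with 8 to 20% mitochondrially encoded UMIs the difference was 3.07, so it did not rest on cells below 8%. That range left 277 untreated MDAMB436 cells, and shares within it were not matched. An uneven share of damaged cells therefore stays open. A response that differs between the lines may explain the pattern, as a hypothesis, but the unnamed treatments may differ, and an unreplicated culture difference stays open.

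MDA-MB-361 is known as an ERBB2-amplified luminal line, but the library labelled MDAMB361 had 9.07 CPM of ERBB2 and correlated with the MDAMB231 library at 0.928, against 0.8197 for its next nearest. This is consistent with cells of the same line under both labels, while a mix with ERBB2-high cells would leave cells with at least 3 ERBB2 UMIs, of which 0 of 892 were found (upper limit 0.413%). The library labelled MCF7s2 reached at most 0.761 with a library of another line, below the 0.855 between the other MCF7 libraries, which argues against another line of this series in the state sampled here, although it was lower still with those MCF7 libraries (0.704 and 0.638). A mix with cells like replicates 1 and 2 is argued against too, since 0 of 4828 cells were assigned to them (upper limit 0.0764%). A line outside the series and an altered state of MCF7 or of another line stay open, and no biological explanation was tested.

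Over its 12 pairs with other libraries of version 3.1.0 the treated MDAMB453 library had 438 barcode matches, where chance gives 23.8 (404 of its barcodes matched any library), a ratio of 18.4 that excludes chance alone. Of the 430 matches with MDAMB231, MDAMB361, MDAMB436-Treated, MDAMB468 or SUM149, 83.7% (360) were assigned to the line of that library, against 1.90% for barcodes not shared, which is consistent with reads carried over between libraries. This did not hold for MDAMB468, where 3 of 23 were assigned to MDAMB468 and 18 to MCF7, with a median of 2510 UMIs here and 679 there. Carry-over of barcodes held in the other matrices cannot account for all kept cells of other lines, since 40% of them (94 of 235, upper limit 46.6%) shared a barcode. Carry-over from libraries outside the series, or from barcodes that the matrices do not hold, could not be checked in this way. The remaining cells were assigned mainly to MCF7 (57), T47D (40) and BT474 (35), and cells of other lines had a median of 1705 UMIs against 15390 in MDAMB453 cells, so their source stays open and no biological explanation was tested.

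The same difference of medians was -0.72 for S phase and -1.28 for MAPK output, also not tested. Of the barcodes removed by the filter 93.5% were assigned to the line of their own library. The share was 100% in BT474 and 99.3% in T47D, which held 2977 and 4185 of the removed barcodes. It was 48.6% in the treated MDAMB453 library and 54.8% in MCF7 replicate 2, and at least 84.2% in every other library. Genes used as markers of other cell types were present in some lines. The fibroblast and muscle list summed to 526 CPM in BT549, of which COL1A2 gave 261 CPM. The immune list summed to 132 CPM in SUM149, with CD68 at 99.97 CPM, the endothelial list to 85.2 CPM in HCC1954, with CDH5 at 45.5 CPM, and the erythroid list to 15.3 CPM in SUM149, all from HBA1.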

How the results depend on the processing

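The alternatives that compared own-line cells, cells with 8 to 20% mitochondrially encoded UMIs, a mitochondrial limit of 40%, cells without shared barcodes, relations without the library labelled MDAMB361, without version 3.0.2 or without MKI67 and TOP2A in the G2/M list, regions without the doubted libraries, and profiles per library were chosen after seeing the data. No paired analysis was possible because each treated condition has 1 library. Of the values that answer a comparison, 294 stayed the same, 36 moved and 1 reversed under an alternative. Of the other values 3444 stayed the same, 466 moved and 3 reversed. A log2 fold or level counted as the same when it kept its sign and changed by at most 1.28. That limit is the root mean square log2 SD of the 3 MCF7 libraries (0.958 for replicates 1 and 2 alone). Many list medians were smaller than this limit, so the counts do not show that such values were stable. Except where a setting itself changes which genes or cells enter, the cause was not tested.

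The counts of genes at least 4-fold apart followed the level and size required. In MDAMB436 the higher and lower counts were 77 and 49 with a minimum of 10 CPM, 11 and 11 with 200 CPM, 119 and 65 with no minimum, and 277 and 189 at 2-fold. In MDAMB453 they were 159 and 129, 41 and 24, 198 and 170, and 555 and 441. Averaging CPM over cells gave 15 and 15 in MDAMB436. The stricter filter, which leaves 23 treated cells, gave 169 and 94 in MDAMB453, and leaving out mitochondrial and ribosomal genes gave 102 lower. Low lists in MDAMB436 numbered 6 without mitochondrial and ribosomal genes, 5 in cells with 8 to 20% mitochondrially encoded UMIs and 5 with a pseudocount of 5 CPM. High lists there numbered 9 in those cells and 7 with members of at least 50 CPM. With that member minimum MDAMB453 had 4 high and 2 low lists. Averaging over cells reversed the G2/M median in MDAMB453 to -0.0900, and the stricter filter reversed CYP1A1 (-1.47) and CYP1A2 (-0.70), which have few UMIs in 23 cells.

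The treated-minus-untreated share of cells with MKI67 or TOP2A reversed to 2.36 points unthinned in MDAMB436, where the treated cells were deeper. In MDAMB453 it was -0.16 points at 2500 UMIs, -21.1 with the stricter filter and -1.63 in own-line cells. The share of the MDAMB453-Treated library assigned to other lines was 22.7% with genes of at least 200 CPM and 33.2% with no cell filter. The median number of overdispersed genes was 32 at 2500 UMIs and 148 with a Fano limit of 2, and windows of 15 genes named 69 regions. The ESR1 relations had no value under the stricter filter and the average over cells, because the lines split into clusters, and r within the larger cluster was -0.286 and -0.140 with PGR. The stricter filter left 15, 43 and 23 cells in BT474, T47D and the treated MDAMB453 library, whose kept cells had median mitochondrially encoded shares of 18.0, 16.7 and 15.7%. Without the libraries labelled MDAMB361 and MCF7s2 the best median of the MCF7 region was 2.86.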

Other observations

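Except for SPANXB1, all values in this part were taken from gene lists fixed before the data were examined. No further test was run on them. Cancer-testis antigen genes, which are normally restricted to germ cells, reached 5 CPM in some lines in different combinations. MDAMB436 had 578 CPM of MAGEA4 and 35.8 CPM of PRAME. MDAMB468 had 75.2 CPM of MAGEA3, 77.2 of MAGEA6, 93.1 of MAGEA12 and 143 of the neighbouring gene CSAG1, and HCC1954 had 65.6 CPM of MAGEA3 and 55.6 of MAGEA6. MAGEA3 and MAGEA6 are near-identical, so their counts may not be separable by 3′ reads, but neither exceeded 19.5 CPM in any other library. SKBr3 had 5 of the 24 list members at 5 CPM or more, the most of any library, with CTAG2 at 124 CPM and MAGEA3 at 19.5 CPM. MDAMB231 had 3, led by CSAG1 at 12.6 CPM, and T47D had 12.1 CPM of GAGE2A and 14.5 CPM of PRAME. Within this list, PRAME alone reached 5 CPM in BT549 (8.01 CPM) and in the library labelled MCF7s2 (23.6 CPM), and CSAG1 alone in the library labelled MDAMB361 (10.7 CPM), which also had 236 CPM of SPANXB1, a gene of this kind outside the list. In treated MDAMB436 MAGEA4 stood at 637 CPM and PRAME at 76.6 CPM.

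Tumour suppressor genes were low in particular lines. SUM149 had 0 UMIs of CDKN2A and of its neighbour MTAP on chromosome 9, where BT549 had 952 and 64.7 CPM. MDAMB231 and the library labelled MDAMB361 had 0.261 and 0.322 CPM of MTAP. RB1 was 1.03 CPM in MDAMB468, 4.35 in SUM149 and 4.37 in MDAMB436, against 48.3 in MDAMB453. PTEN was 2.39 CPM in SUM149, and SMAD4 0.934 CPM in MDAMB468.

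Cytokine genes also differed between lines. The NF-kB and cytokine list had a mean log2(CPM + 1) of 6.17 in MDAMB436 and 6.03 in SUM149, against 0.89 in MDAMB453 and 1.35 in SKBr3. LCN2 reached 3503 CPM in SUM149 and 1813 CPM in HCC1954. SAA1 was 926 CPM in SUM149 and 592 CPM in the library labelled MDAMB361, and the neutrophil attractant CXCL8 was 479 CPM in MDAMB436 and 384 CPM in SUM149. Antigen presentation genes were highest in HCC1954 (6.17) and T47D (5.45) and lowest in MDAMB453 (2.48).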
